A study of Mus musculus with 6 samples.

How the data were processed

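Pancreatic total RNA, extracted with TRIzol per the labels, was measured on 6 Affymetrix MG-U74Av2 arrays. The deposited values are intensities on a linear scale, 1 per probe set and array. The steps that made them, the software and any scaling target are not given in the sources used here. Their means after leaving out 2% of the values at each end lay between 500.27 and 500.3 on all arrays, so the arrays were taken as already scaled and kept so. The table held 0 values at or below zero and no detection calls.

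Groups came from the genotype in the sample descriptions, and replicate numbers 1 to 3 from the suffix of the sample titles. Each array held the RNA of a single mouse, per the labels, so p-values rest on the spread between mice together with that of the measurement. In a fit without a block for the suffix, that spread also holds whatever arrays of the same suffix share. The label of control replicate 1 names the entire pancreas, and those of the other 5 arrays the pancreas. Of the 12488 probe sets, 10855 had 1 gene symbol in the platform annotation, 396 had several and 1237 had none; 10839 were matched by gene identifier to RefSeq gene names of assembly GRCm38.p6. Probe sets with several symbols were tested but not named.

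Values under the pooled 20th percentile (47.6) were set to it and log2 was taken. The 66 control probe sets were left out, and a probe set was kept if at least 3 of 6 arrays lay above the pooled 40th percentile (140.2), which left 7739 probe sets of 5804 named genes. CF was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with an intensity trend, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. All adjusted p-values are from limma unless camera or fry is named. Folds are on the floored log2 scale, and understate changes of dim genes.

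Before the data were examined, 35 lists of pathway genes and cell type markers were fixed. They were tested with camera at a preset correlation of 0.01, beside an estimated correlation and fry, with 1 probe set per gene, that of highest mean, over lists with at least 5 measured genes. Named genes followed a rule also fixed then: up to 12 genes per direction that passed and did not overlap between groups, filled up to 8 per direction by smallest p where fewer passed, plus Cftr and Gast, plus up to 4 members of smallest p of each list described. Further probe sets of a named gene, and the remaining Reg genes, were given after their values were seen. Some probe sets too dim to test are left out.

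Whether the title suffixes pair the samples was decided from the arrays' deviations, not from the calls of either fit. Deviations from the group means correlated at 0.23 to 0.26 between samples with the same suffix and at -0.18 to -0.05 between the others, and all 3 control arrays correlated best, among the CF arrays, with that of their own suffix. Every pair exceeded 0.1, so the suffix was taken to pair the samples. SEs and adjusted p-values are still from the fit without the block unless it is named. The fit with the suffix as a block is given where it changed a call or count, and for the genes past the threshold, Lrg1 and Acta2.

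The fit was tested on simulated data for the 7739 probe sets, with 200 changed in each of 5 runs. It recovered 24.5% of those changed by 1 on the log2 scale, 70.2% of those changed by 2 and 91.8% of those changed by 4, and called 31 of 37695 unchanged ones. These shares may be too high for the real data, where 5 probe sets were called. The adjusted threshold is easier to pass when more probe sets change. Nor was an effect of the title suffix simulated. Simulated lists shifted by 1 were called in 5 of 5 runs, and 0 of 150 unshifted lists were called. The simulated genes varied independently of each other. The list result therefore does not measure false calls where the genes of a list move together. Alternatives covered the scaling, the floor, the filter, the variance model, array weights, the block, the threshold, the list test and leaving out each array.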

Results

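Total RNA of the pancreas was measured on 6 one-colour oligonucleotide arrays, 3 from control mice with intact Cftr and 3 from mice lacking Cftr, called CF here. Cftr encodes the epithelial chloride and bicarbonate channel that is defective in cystic fibrosis. All mice were males aged 56 to 58 days, carried a single working gastrin allele, had a mainly black6 background with a small 129Sv share, and were fed the peptide-based diet Peptamen, which guards against blockage of the gut. The comparison asks which pancreatic transcripts differ when Cftr is absent. Each array gave 1 intensity for each of 12488 probe sets, with array medians between 207.8 and 234.4, and 7739 probe sets were bright enough to be tested. The number of arrays, 3 per group, limits the precision of every value.

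Of the genes past the threshold, 2 that encode secreted lectins of the Reg family rose furthest in the CF pancreas. Reg3g, which encodes an antibacterial lectin, rose 93.3-fold, from 570 ± 421 to 36545 ± 950 (intensity, mean ± SD, n = 3 per group; log2 difference 6.54 ± 0.72 SE, adjusted p = 0.021). That difference was 5.50 without control replicate 2 and 7.13 without control replicate 3. Reg3a rose 6.09-fold, from 12973 ± 5775 to 74303 ± 9032 (log2 difference 2.61 ± 0.29, adjusted p = 0.021). Serpina10, which encodes a plasma inhibitor of coagulation proteases, rose 2.70-fold, from 656 ± 57 to 1768 ± 14 (log2 difference 1.43 ± 0.17, adjusted p = 0.023). These 3 genes accounted for all 5 probe sets past the threshold, each with its 3 CF values above its 3 control values, and 0 probe sets fell.

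**Figure D1:**
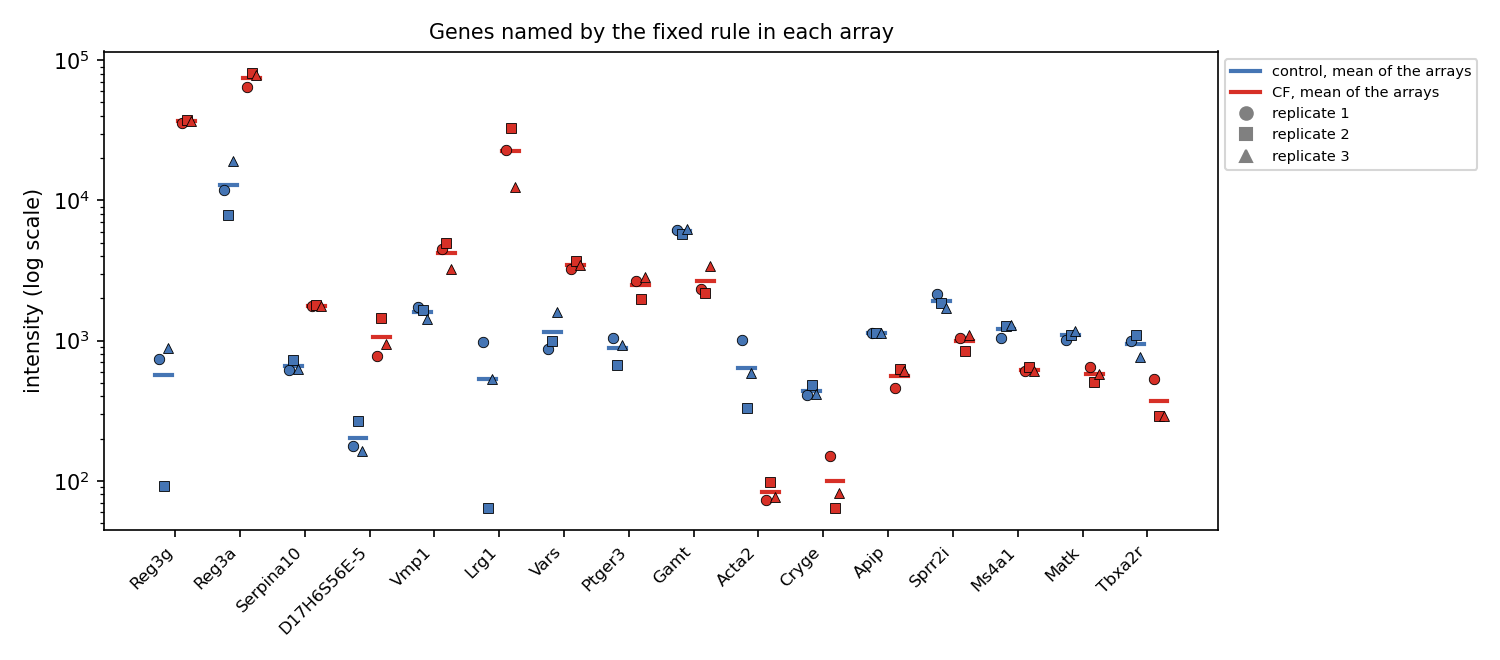
Intensity on a log axis of the 16 genes named by the fixed rule, in each control (blue) and CF (red) array, with symbols for the replicate number and bars for group means. The CF values of Reg3g lie between 35523 and 37400 and its control values between 92 and 883; for all 16 genes the groups do not overlap, though 3 genes passed the test.

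Both probe sets of Reg3g and both of Reg3a passed, with different sizes. The second Reg3g probe set rose 30.7-fold (log2 difference 4.94 ± 0.26, adjusted p = 0.00019) and the second Reg3a probe set 26.4-fold (4.72 ± 0.48, adjusted p = 0.020; 4.16 without control replicate 2 and 5.32 without control replicate 3). For Reg3a, the probe set that was brighter in controls gave the smaller fold; it read up to 80716 in CF, where the array maxima were 92020 to 135426. Reg3b had values of 14778 ± 6375 in controls and 57169 ± 5978 in CF on its dimmer probe set (log2 difference 2.05 ± 0.31, adjusted p = 0.077), and 53620 ± 5345 against 82009 ± 9085 on its brighter one (0.61 ± 0.16, adjusted p = 0.30). Reg2 measured 50625 ± 3011 in controls and 73071 ± 6726 in CF on its brighter probe set (0.53 ± 0.14, adjusted p = 0.37), and its dim probe set pointed the other way (-1.02 ± 0.58, adjusted p = 0.75). Reg1 differed by -0.13 ± 0.16 on its bright probe set (adjusted p = 0.91), near the top of the range, where a change may be compressed. Its dimmer probe set differed by 0.23 ± 0.21 (adjusted p = 0.87). As a list of 5 measured genes, the Reg family was higher in CF (camera adjusted p = 2.6e-06; adjusted p = 0.45 with an estimated correlation), with 2 members risen, 0 fallen and 3 not past the threshold. Adjusted over the list alone, 4 members were higher. The Reg transcripts are similar in sequence, and how far each probe set reads its relatives was not measured.

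**Figure D2:**
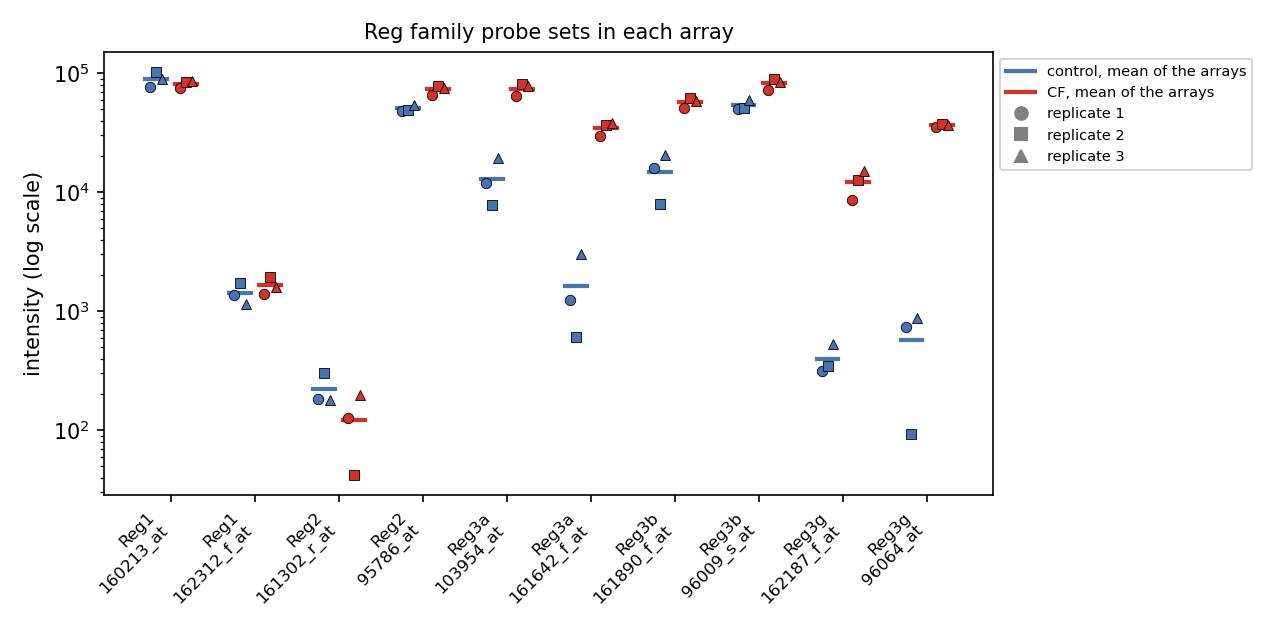
Intensity on a log axis of all 10 tested Reg family probe sets, in each control (blue) and CF (red) array, with symbols for the replicate number and bars for group means. The less bright Reg3a probe set moves from a mean of 1622 in controls to 34878 in CF. The bright Reg1 probe set averages 89725 and 81844, near the top of the range, where changes may be compressed.

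Of the next genes by p, given as not past the threshold, 5 were higher in CF. Lrg1, which encodes a secreted leucine-rich glycoprotein, measured 528 ± 461 in controls and 22690 ± 10267 in CF (log2 difference 6.02 ± 0.87, adjusted p = 0.068). It passed at 6.83 without control replicate 1 (adjusted p = 0.042) and at 4.85 without control replicate 2 (adjusted p = 0.0064). Its adjusted p was 0.24 without CF replicate 1, 0.38 without CF replicate 2 and 0.41 with no filter. Vmp1, an endoplasmic reticulum membrane protein needed for autophagosome formation, measured 1604 ± 151 and 4219 ± 879 (1.38 ± 0.19, adjusted p = 0.068). Vars, the valyl-tRNA synthetase, and the directly neighbouring D17H6S56E-5 differed by 1.63 ± 0.24 (adjusted p = 0.068) and 2.36 ± 0.31 (adjusted p = 0.052). Ptger3, a prostaglandin E receptor, differed by 1.51 ± 0.23 (adjusted p = 0.077), and its dimmer second probe set by 1.40 ± 0.58. With the replicate number as a block, Vmp1, D17H6S56E-5 and Ptger3 each had an adjusted p of 0.040. Of single arrays, leaving out control replicate 2 let D17H6S56E-5 pass (0.028), control replicate 3 Vars (0.016) and CF replicate 3 Vmp1 (0.042).

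The 8 genes with the smallest p among those lower in CF did not pass either, though Gamt did without CF replicate 3 (-1.42, adjusted p = 0.042) and with array weights (0.038), and Acta2 without control replicate 2 (-3.23, adjusted p = 0.037) and with array weights (0.036). Gamt, which makes creatine from guanidinoacetate, measured 6048 ± 267 in controls and 2650 ± 667 in CF (log2 difference -1.22 ± 0.19, adjusted p = 0.080), and its second probe set differed by -0.68 ± 0.18. Acta2, the smooth muscle actin, measured 642 ± 341 and 83 ± 14 (-2.82 ± 0.44, adjusted p = 0.082). Ms4a1, the B cell surface protein CD20, differed by -0.95 ± 0.18 (adjusted p = 0.15), but by 0.00 ± 0.57 on a dimmer probe set. Cryge, a lens crystallin, differed by -2.23 ± 0.40 on 1 probe set (adjusted p = 0.12) and by 1.46 ± 0.57 on another. Apip, an enzyme of methionine salvage, and the thromboxane receptor Tbxa2r differed by -1.02 ± 0.20 and -1.40 ± 0.29. The remaining pair, Sprr2i and the kinase gene Matk, differed by -0.94 ± 0.18 and -0.93 ± 0.19.

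Limma called 5 probe sets at an adjusted p under 0.05, 17 under 0.1 and 571 at an unadjusted p under 0.05. Were the arrays independent, 387 would be expected by chance, but the suffix was taken to pair them. Other splits of the arrays into 3 and 3, made later, gave 163, 130 and 144 where they part all pairs. Splits that do not part all pairs gave 279 to 924. In 1005 probe sets, 13.0%, the 2 groups did not overlap, against 10% by chance for independent arrays. Of these, 212 also differed at least 2-fold. The replicate block gave 10 calls, all higher in CF, among them the 5 of the unblocked fit. Beside those given above it added Htt (1.12 ± 0.11, adjusted p = 0.041), named after its value was seen, and a probe set without a symbol. With the block, adjusted p was 0.04 for the Reg3g probe set with the larger fold and for the brighter Reg3a probe set. It was 0.041 for Serpina10, 0.13 for Lrg1 and 0.17 for Acta2, and the last 2 passed in neither fit. The number of calls was 1 without CF replicate 1, 1 without CF replicate 2, 8 without CF replicate 3 (4 higher and 4 lower, 2 of them among the 5) and 11 without control replicate 2 (10 higher and 1 lower), and the dimmer Reg3g probe set was called in each of these. The Reg3g probe set with the larger fold lost its call without CF replicate 1, 2 or 3 (adjusted p = 0.14, 0.15 and 0.062), as did the brighter Reg3a probe set (0.12, 0.15 and 0.063) and Serpina10 (0.18, 0.17 and 0.063); that Reg3a probe set also lost it without control replicate 1 (0.066), and Serpina10 without control replicate 1 (0.096) or 3 (0.11). The call also ended with a robust variance fit for that Reg3g probe set (adjusted p = 0.075), and, for the same Reg3g and Reg3a probe sets and Serpina10, with no filter (0.33 for Reg3g, 0.32 for Reg3a and 0.098 for Serpina10) and no intensity trend (0.082 for each), though the dimmer Reg3g probe set passed with the robust fit (0.00019) and with no trend (0.0091).

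The 2 genes that define the mice gave no check of the labels. Of 3 Cftr probe sets, 1 was bright enough to test and measured 293 ± 62 in controls and 382 ± 78 in CF (log2 difference 0.38 ± 0.29, adjusted p = 0.82). The other probe sets for Cftr averaged 10.2 and 11.1 in controls and 7.2 and 28.7 in CF, all under the floor of 47.6. Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so they check nothing, and the arrays are called by their labels. The brightest Gast probe set, for the hormone gastrin, measured 148 ± 25 in controls and 99 ± 14 in CF and was too dim to be tested.

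Genes of connective tissue, fat and immune cells were lower in CF as lists, and duct cell genes were higher, while 0 members of these lists passed the threshold over all genes. Of 43 extracellular matrix and stellate cell genes, 33 were lower in CF (median log2 difference -0.30; camera adjusted p = 9e-06; adjusted p = 0.45 with an estimated correlation). The members with the smallest p were Igfbp4 (-1.02 ± 0.25), Col15a1 (-1.29 ± 0.31), Col6a2 (-0.72 ± 0.22) and Col6a3 (-1.50 ± 0.56), the last 3 encoding collagen chains. Of 14 adipocyte markers, 13 were lower (median -0.92; camera adjusted p = 0.00019; adjusted p = 0.55 with an estimated correlation). Adipoq, the fat cell hormone adiponectin, measured 2559 ± 2762 in controls and 278 ± 384 in CF, and the hormone gene Retn 515 ± 437 and 96 ± 44. The other leading members, Aoc3 and Agt, differed by -1.18 ± 0.44 and -1.09 ± 0.46.

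Among 11 lymphocyte markers, 10 were lower in CF (median -0.53; camera adjusted p = 0.0013; adjusted p = 0.50 with an estimated correlation). They were led by Ms4a1, followed by Cd37 (-0.78 ± 0.35), the joining chain of antibodies Jchain (-1.08 ± 0.63) and the immunoglobulin heavy chain Ighm (-1.48 ± 0.95). Among 20 macrophage and granulocyte markers, 16 were lower (median -0.41; camera adjusted p = 0.011; adjusted p = 0.78 with an estimated correlation), including Laptm5 (-0.71 ± 0.20), Cd68 (-0.86 ± 0.27) and Tyrobp (-0.89 ± 0.38), while Cd14 differed by 0.41 ± 0.20. Among 17 interferon-stimulated genes, 13 were lower (median -0.61; camera adjusted p = 0.015; adjusted p = 0.78 with an estimated correlation), with Gbp3 at -0.63 ± 0.37, Irf8 at -0.76 ± 0.47, Rsad2 at -0.95 ± 0.64 and Gbp2 at -0.77 ± 0.53. The adipocyte score moved with these lists: it was 10.6, 8.31 and 9.76 in control replicates 1, 2 and 3, and 9.07, 8.14 and 8.34 in the CF replicates. Control replicate 1, the highest, is the array whose label names the entire pancreas. The Gapdh 3'/5' ratio, a sign of RNA quality, averaged 1.03 ± 0.36 in controls and 0.78 ± 0.08 in CF, a difference of -0.25 that was -0.034 without control replicate 2 (1.45), and the Actb ratio averaged 1.94 ± 0.21 and 1.94 ± 0.20.

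Of 18 duct cell markers, 12 were higher in CF (median 0.09, mean 0.24; camera adjusted p = 0.044; adjusted p = 0.45 with an estimated correlation), a call that ended with the replicate block (adjusted p = 0.057). Elf3, an epithelial transcription factor, measured 859 ± 54 in controls and 1625 ± 84 in CF (0.92 ± 0.16, adjusted p = 0.11), and the keratin gene Krt18 3462 ± 205 and 5344 ± 805 (0.62 ± 0.16, adjusted p = 0.31). The tight junction gene Cldn4 and the adhesion gene Epcam differed by 1.58 ± 0.54 and 0.66 ± 0.29. Adjusted over the list alone, 2 duct markers were higher, 1 lymphocyte marker was lower, and 0 members of the matrix, adipocyte, macrophage and granulocyte, or interferon lists passed.

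**Figure D3:**
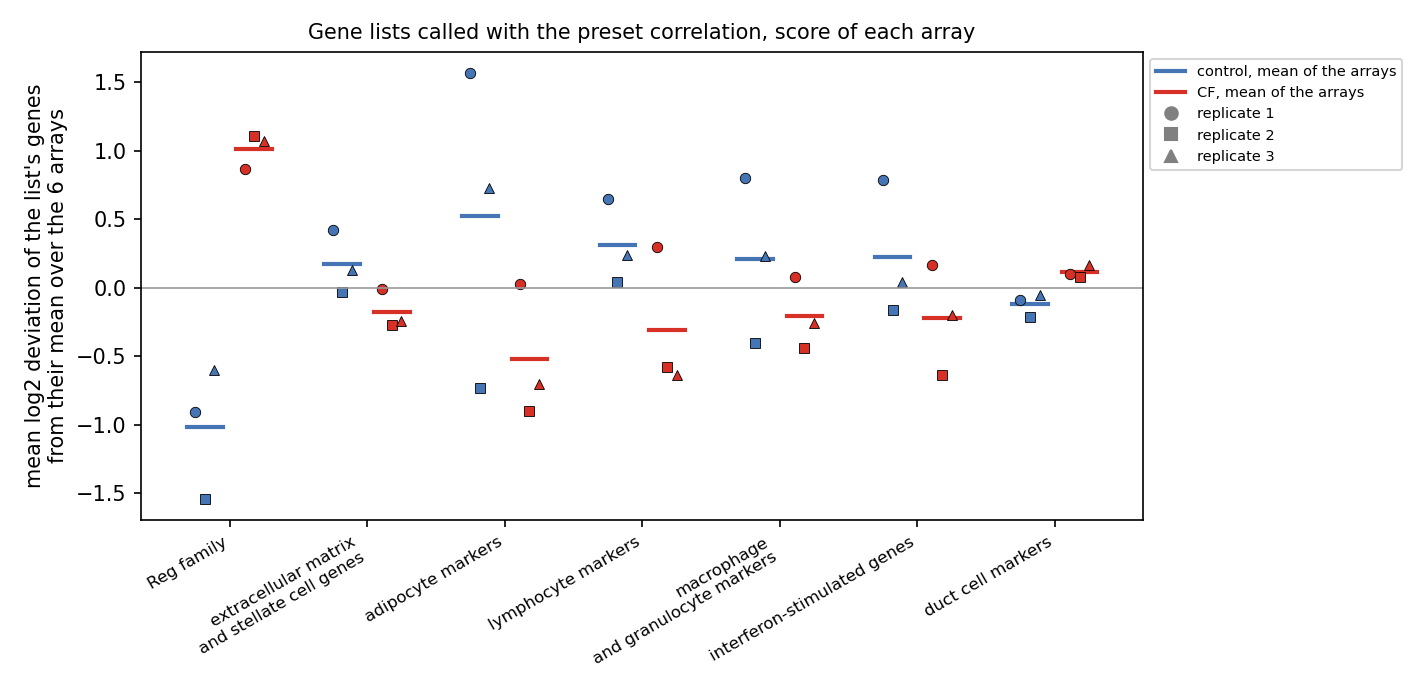
Score of each array for the 7 lists called with the preset correlation, as the mean log2 deviation of the list's genes from their mean over the 6 arrays, for control (blue) and CF (red) arrays with bars for group means. Duct scores of the 3 CF arrays, 0.08 to 0.17, lie above all control scores, while adipocyte scores of the controls spread from -0.73 to 1.57.

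In all, camera called 7 of 35 lists, 2 higher and 5 lower in CF, and 0 were called with an estimated correlation or by fry for a shift in a single direction (lowest adjusted p = 0.080). For change in either direction, fry called 6 lists, those of the Reg family, duct, mesothelium, smooth muscle, acute phase proteins and cytokine signalling. Without control replicate 1 the adipocyte (median -0.43, adjusted p = 0.068), macrophage and granulocyte (-0.17, 0.39), interferon (-0.26, 0.38) and duct (0.13, 0.068) calls ended. The duct call also ended without control replicate 2 (median 0.04, adjusted p = 0.20) and the interferon call without CF replicate 2 (-0.26, 0.22). Quantile normalization (adjusted p = 0.11), no filter (0.056) and a filter at the 60th percentile (0.16) ended the duct call, and that filter the interferon call (median -0.28, adjusted p = 0.21). Among calls that held, the macrophage and granulocyte median was -0.69 without control replicate 2, the lymphocyte median -0.85 without CF replicate 1, and the duct median 0.27 without control replicate 3 and 0.16 and 0.18 without CF replicates 1 and 2. The interferon call also held with the floor at the 40th percentile, at a median of -0.33. In number, 3 lists, the Reg, matrix and adipocyte lists, were called without CF replicate 3 and 13 lists without CF replicate 1.

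The digestive function of the gland showed no list call. Of 18 acinar digestive enzyme and granule genes, 14 were lower by small amounts (median -0.15, camera adjusted p = 0.40), with Sycn at -0.30 ± 0.17 and the elastase gene Cela2a at -0.24 ± 0.17, while Itih4 differed by 1.79 ± 0.27 (adjusted p = 0.077) and Cuzd1 by 0.36 ± 0.19. Several enzyme probe sets read near the top of the range, such as Ctrb1 at 111633 and Ctrl at 106958 in controls. Array maxima were 92020 to 135426, so changes of these genes may be compressed, and small differences do not show unchanged expression. Several amylase and trypsin genes share probe sets and are not named. Median differences were 0.21 for acinar transcription factors, 0.11 for stimulus-secretion coupling, 0.09 for chaperones and the unfolded protein response, 0.01 for ion and water transport, 0.02 for gut peptides and their receptors, and -0.29 for islet cell genes. They were 0.02 for acute phase proteins, 0.13 for cytokines and their signalling, -0.26 for antigen presentation, -0.09 for tissue injury and metaplasia genes, 0.03 for apoptosis and p53 targets, 0.11 for cell cycle genes and -0.13 for immediate early and heat shock genes. For metabolism, medians were -0.09 for amino acids and one-carbon units, -0.18 for cholesterol synthesis, 0.09 for fatty acid oxidation, -0.06 for oxidative phosphorylation and -0.09 for antioxidant genes, and that of cytosolic ribosomal proteins was 0.09. Among markers of other tissues, medians were -0.32 for endothelium, -0.37 for mesothelium, -0.14 for smooth muscle, -0.02 for skeletal muscle, -0.35 for liver, 0.14 for intestinal epithelium, 0.00 for erythroid cells and -0.02 for neural cells. Camera adjusted p-values of these 28 lists ran from 0.058 to 0.92. For the cell cycle, gut peptide, stimulus-secretion and injury lists the median and the direction of camera differed in sign.

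Arrays of the same group correlated at r = 0.865 to 0.920 across genes, which are not independent replicates, and arrays with the same title suffix in the other group at 0.881 to 0.921. The first 3 principal components held 29.8, 25.8 and 20.4% of the variance. On the second component all 3 control arrays lay at or below -11.1 and all 3 CF arrays at or above 13.7. For independent arrays, 10% of components part the groups so by chance. On the other 2 components the groups overlapped. The first was at -27.6, 33.3 and -25.4 in control replicates 1, 2 and 3, and at 1.4, 27.4 and -9.2 in CF. The third followed the order of the suffixes, at -22.1, 1.4 and 15 in controls and -25.9, 1.4 and 30.2 in CF.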

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

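All tests in this part, other than the alternatives named, were chosen only after the results were seen. Of the 66 control probe sets that stayed out of the comparison, 2 were higher in CF with no overlap and by at least 2-fold in mean log2 value (log2 differences 1.07 and 2.04), both for pyruvate carboxylase (Pcx). One measured 565 ± 258 in controls and 1090 ± 98.6 in CF, the other 110 ± 11.8 and 505 ± 281 (SD, n = 3). The ordinary Pcx probe sets, at 549 against 654 and 170 against 232, overlapped between the groups.

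For the rise of Reg3g and Reg3a, the scaling of the arrays is argued against, since under quantile normalization the Reg3g probe set of smallest p still differed by 4.89 on the log2 scale (adjusted p = 0.00018). Reg3g probe sets may in part read Reg3a RNA: on the less bright probe sets the log2 differences of the 2 genes were 0.22 apart (95% interval -1.23 to 1.67). The brighter Reg3g probe set rose by 1.82 more than the less bright Reg3a probe set, with a 95% interval off 0 between groups (0.25 to 3.40) but not within pairs (-0.29 to 3.94), and the brighter Reg3a probe set was not used, as its rise may be compressed near the top of the range, so a rise of Reg3g of its own and such reading cannot be told apart. The Reg genes lie on the same chromosome as Cftr, and DNA of the 129Sv strain linked to the altered allele might reach them; of the 117 measured genes between, 6 had an unadjusted p under 0.05, where equally long runs elsewhere had 9 at the median and 5 and 14 at the 5th and 95th percentiles, which leaves this open. An effect of the missing channel also stays open.

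For the lower stromal, fat and immune genes in CF, a smaller share of all non-acinar tissue alike would also lower the duct markers. Their score was 0.24 higher in CF with no overlap between groups. The score does not tell the number of duct cells from expression per cell, so this explanation stays open. Among lists that camera did not call, 11 of 12 endothelial, 13 of 19 islet, 6 of 9 smooth muscle, 7 of 9 neural and 5 of 9 mesothelial genes were lower. Going the other way, 4 of 7 erythroid and 3 of 5 intestinal epithelial genes were higher. For RNA quality, the Actb 3'/5' ratio differed by -0.0031 between group means (SD within groups 0.20) and the Gapdh ratio by -0.25 (SD 0.27), or by 0.10 and -0.034 without control replicate 2, where the list medians were -1.27 for adipocytes, -0.69 for macrophages and granulocytes and -0.41 for matrix genes. Within pairs 1, 2 and 3 Actb differed by 0.0014, -0.019 and 0.0082, Gapdh by -0.075, -0.70 and 0.035, and the adipocyte score by -1.54, -0.17 and -1.42, which runs against RNA quality, though 2 ratios on 3 pairs are too few to exclude it. An effect of genotype on these tissues, not separately tested, stays open, as does, for the adipocyte list, an amount of attached fat that varies between dissections: the list's score ranged over 2.29 among the controls, against 1.04 between the group means. Within pairs it was lower in CF in 3 of 3, with a range of 1.37, and camera with its preset correlation called the list with the replicate block (adjusted p = 7.4e-06), whereas without the block the call was lost with an estimated correlation (adjusted p = 0.55), by fry (0.61) and without control replicate 1 (0.068). The macrophage and granulocyte, interferon, lymphocyte and matrix scores were also highest in control replicate 1 (deviations 0.8, 0.79, 0.65 and 0.42). Attached tissue that varies between dissections stays open for these lists too.

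Serpina10 passed the test, and Lrg1 and Itih4, which also encode plasma proteins, were higher without passing; they were grouped after their values were seen, while the fixed acute phase list was not called (camera adjusted p = 0.18, median 0.02), with Cfb at -1.16 ± 0.48, Hp at -1.03 ± 0.45 and Serpina3n at -0.40 ± 0.39. Liver tissue as the whole source is argued against by abundant liver transcripts, with Alb at -0.32 (upper 95% limit 0.38) and Apoa2 at -0.38. The liver list also runs against it, with 1 of its 8 measured genes higher. Ttr, at -0.54, counts among these 8 but is also in the islet list (median -0.29), so its value does not bear on liver tissue alone. Named after their values were seen, Kng1 (1.41 ± 0.29), Serpina1c (1.07 ± 0.18) and the liver marker Ahsg, too dim to test (85.0 ± 10.1 in controls and 186 ± 92.6 in CF), were also higher. More granulocytes or macrophages are argued against by their marker score, with an upper 95% limit of 0.64, against 1.43 for Serpina10. Expression of these genes by pancreatic cells lacking Cftr is a possible explanation that these arrays did not test.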

How the results depend on the processing

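Alternatives were planned before the data were examined, except the splits of the arrays. Of 20 alternatives, 9 kept the count of called probe sets within 1.5 times of 5, among them both other scalings. The count was 10 with a floor at the 40th percentile, 0 with no filter (lowest adjusted p = 0.098, 773 at an unadjusted p under 0.05, 12422 tested), 3 with no intensity trend (all higher, 1 of them among the 5), 12 with array weights (10 higher, 2 lower), 10 with the replicate block, 17 at an adjusted p under 0.1, 212 by 2-fold change and no overlap, and 1 to 11 leaving out single arrays. Of the 16 named genes, each counted on the 1 probe set given first in the results, 3 passed. The count was 7 with the floor at the 40th percentile, 5 with a pseudocount, 0 with no filter, 0 with no trend, 8 with array weights, 6 with the replicate block, 10 at an adjusted p under 0.1, 13 by 2-fold change and no overlap, and 0 to 6 leaving out single arrays. The dimmer Reg3g probe set, not counted here, passed with no trend (adjusted p = 0.0091) and without CF replicate 1 (0.00057) or 2 (0.004). Over the alternatives, adjusted p on these probe sets ran from 4.3e-06 to 0.33 for Reg3g, 0.0047 to 0.32 for Reg3a and 0.011 to 0.18 for Serpina10. Among genes not past the threshold, it ran from 0.0064 to 0.41 for Lrg1, 0.021 to 0.31 for D17H6S56E-5 and 0.028 to 0.32 for Vmp1. The range was 0.016 to 0.38 for Vars, 0.04 to 0.33 for Ptger3, 0.038 to 0.4 for Gamt and 0.036 to 0.37 for Acta2. No named gene and no called list changed direction under any alternative run. For the named genes this says little: their groups did not overlap, so leaving out an array could not turn the direction. The 7 called lists became 0 with an estimated correlation, 0 with fry, 11 with the mean of a gene's probe sets and 3 to 13 leaving out single arrays; the block gave 6. The mean correlation of arrays within groups, 0.896, was 0.924 with the floor at the 40th percentile, 0.933 with no filter and 0.890 to 0.909 leaving out single arrays. The Cftr difference ranged from 0.20 to 0.52 and never passed. The block changed no other call than those given here and in the results. The causes were not tested. Of the 10 splits of the 6 arrays, 2 gave at least 5 calls, the real one and another with 9, and 3 called at least 7 lists, the highest other 10; 10 splits are too few for a share under 0.05. Of the 4 splits that part all pairs, the other 3 gave 0 calls and at most 4 lists, but 4 splits are too few for such a share as well. At an unadjusted p under 0.05 these 3 gave 163, 130 and 144 probe sets, against 571 for the real split. Splits that do not part all pairs gave up to 924. No detection calls were used here, so signal over background limits dim genes to an unknown degree.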

Other observations

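Of 38 genes of amino acid and one-carbon metabolism, 15 were higher and 23 lower in CF and 0 passed over all genes, with no list call (camera adjusted p = 0.45; fry for change in either direction, adjusted p = 0.051). Beside Gamt, Sat1, which acetylates polyamines for their breakdown, measured 805 ± 227 in controls and 2350 ± 454 in CF (mean ± SD, n = 3; log2 difference 1.57 ± 0.26 SE, limma adjusted p = 0.099). Mthfd2, a mitochondrial folate enzyme, measured 6721 ± 518 and 4392 ± 1051 (-0.64 ± 0.19, adjusted p = 0.44), and Ahcy, which hydrolyses adenosylhomocysteine, 11941 ± 2894 and 21139 ± 6467 (0.81 ± 0.26, adjusted p = 0.51). Adjusted over the list alone, 1 of these 38 genes was higher, Sat1, and 1 lower, Gamt. In the fatty acid list the thioesterase gene Acot1 differed by 1.46 ± 0.32 and Hadh by -0.72 ± 0.18, 1 higher and 1 lower of 25 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.17).

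Of 15 genes of cytokine signalling, 9 were higher and 6 lower in CF, not called by camera (adjusted p = 0.24) but called by fry for change in either direction (adjusted p = 0.048). Socs3, a feedback inhibitor of cytokine receptors, measured 128 ± 73 in controls and 436 ± 77 in CF (1.94 ± 0.49, adjusted p = 0.30), and the adhesion molecule gene Vcam1 198 ± 53 and 61 ± 16 (-1.64 ± 0.52, adjusted p = 0.50). Of 31 immediate early and heat shock genes, 11 were higher and 20 lower, with no call by camera (adjusted p = 0.60) or fry for either direction (adjusted p = 0.43). Gadd45g differed by 1.26 ± 0.26 (adjusted p = 0.19). In this list 4 lower genes and 1 higher one did not overlap between groups, where 10% do by chance for independent arrays. Among the lower ones, the heat shock gene Hspa1a differed by -1.59 ± 0.44 (adjusted p = 0.37) and Jund by -0.62 ± 0.19 (adjusted p = 0.47). Junb, given after its values were seen, differed by 2.14 ± 0.35 (adjusted p = 0.099) on its dimmer probe set and by 1.03 ± 0.38 (adjusted p = 0.6) on its brighter one. The 13 acute phase genes, 7 higher and 6 lower, were not called by camera (adjusted p = 0.18) but by fry for either direction (adjusted p = 0.024). Of the acute phase genes, Cp, the copper carrier ceruloplasmin, lay under the floor in all 3 controls and was at least 8.24-fold higher in CF (adjusted p = 0.16). Adjusted over the list alone, 3 of 13 acute phase genes were higher, Lrg1, Itih4 and Cp, and 0 were lower. Agr2, a disulfide isomerase of mucus-secreting cells, measured 256 ± 49 and 581 ± 123 (1.18 ± 0.28, adjusted p = 0.25), and Cpe, which trims peptide hormones, 1571 ± 313 and 554 ± 297 (-1.61 ± 0.35, adjusted p = 0.20).

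The Actb 3'/5' ratio followed the title suffix: 1.74, 2.16 and 1.93 in control replicates 1, 2 and 3, and 1.75, 2.14 and 1.94 in the CF replicates with the same suffixes. No annotated gene lay between D17H6S56E-5 and Vars, and both were higher in all 3 CF arrays.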
